A study of Mus musculus with 11 samples.

How the data were processed

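The series measured polyadenylated RNA in full-thickness distal colon of 6 wild-type (WT) mice and 5 mice homozygous for a knockout of Nrg4 (KO). Nrg4 encodes neuregulin-4, a ligand of the receptor tyrosine kinase ErbB4. Per the labels' protocols, the genotypes were mixed in shared cages from 9 weeks of age, the animals were dissected at 11 to 12 weeks, both sexes were used, and stranded mRNA libraries were read as single-end reads of 75 nt. The labels give each mouse a number and a cage but no sex. Cage A held 2 WT and 2 KO mice, cage B held 2 WT and 2 KO mice, and cage C held 2 WT mice and 1 KO mouse. Mice are named here by genotype and mouse number (WT-2, KO-1 and so on).

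Per the submitters' processing notes, CASAVA, kallisto and sleuth were used with the mm10 build; their versions are not given in the sources used here. Per the file headers and its class column, the deposited table lists principal transcripts only, as the APPRIS annotation defines them, with values in TPM (transcript abundance scaled for transcript length and library total) per transcript and mouse. The table had 29213 rows, of which 405 repeated another row and were dropped, leaving 28808 transcripts of 22243 genes. The summed TPM of a mouse ranged from 558446 to 770986, lower than the full TPM total. Other transcripts are left out of the table, and any rescaling of the columns would also change these sums. TPM keeps no sequencing depth, so the number of reads per library is unknown here and no counting interval is given. Median-of-ratios factors between mice lay between 0.978 and 1.04; whether the authors rescaled the columns is not given in the sources used here.

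Per the file headers, the same table carries the authors' own comparison of the genotypes: a p-value and q-value per transcript for 14763 transcripts, a deposited log2 ratio, the mean natural log of the normalized estimated count, a likelihood-ratio score, and other deposited columns of sleuth's residual sums and variance components. The deposited log2 ratio equalled the log2 of the mean KO over the mean WT TPM of the row. The deposited residual sums of squares were set beside sums recomputed from reduced models: the median absolute difference was 4.42% with cage as the reduced model and 30.5% with an intercept only, over 3358 abundant transcripts, so the authors' model appears to have held cage, which no label states.

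TPM of transcripts of a gene were summed. Coordinates are from GENCODE M21 (GRCm38, the assembly named mm10), in which 22241 of the 22243 gene identifiers were found. Genes with at least 1 TPM in at least 5 mice (the size of the smaller group) were tested, which left 10756 genes. The planned test was a count test, with limma as the stated alternative where the table held no counts. As the table held TPM, limma 3.58.1 (R 4.3.3) was used with a mean-variance trend on log2(TPM + 0.5), with cage and genotype as terms and Benjamini-Hochberg adjustment at a false discovery rate (FDR) of 0.05. The planned filter was defined on counts, so the TPM filter was set after the table, with the authors' p-values in it, was opened, and before any test was run here. A log2 fold change is KO against WT on the log2(TPM + 0.5) scale, which understates the change of low genes; ± after it is the standard error of the fit. Means of TPM carry the standard deviation (SD).

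Cage was tested with an F test on both cage terms, and the dependence of the genotype difference on cage with an F test on both interaction terms. For 34 gene lists fixed before the data were examined, camera was run with a preset inter-gene correlation of 0.01 and again with an estimated correlation, and fry was run beside it. The share of genes past the threshold within 10 Mb of Nrg4 was compared with all other genes by a two-sided Fisher's exact test. Genes named in the text follow a rule fixed at the same time: Nrg4, then, because fewer than 10 genes passed, the 20 genes with the smallest p, then the 2 members of each list with the smallest p, then the 6 genes with the smallest p in each of the cage and interaction tests, leaving out unnamed gene models and antigen receptor segments. A gene that the rule names is not reported here. Other genes are named as chosen after their values were seen.

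On simulated data with the same genes and mice, the genotype test recovered 69% of 100 genes changed 2-fold and 93% of 100 genes changed 4-fold, with 5.26% of calls false, and called 0 genes when no gene was changed. The cage test recovered 92.5% of 200 genes changed 4-fold in cage B, and the interaction test 74.5% of 200 genes given an 8-fold interaction. Each simulation with changed genes changed 200 at once and drew noise independently for each gene. With fewer changed genes the adjustment is stricter, and real genes vary together. The recovered shares are thus no estimate of power for a comparison that calls 4 genes. Log2 values of any pair of mice correlated between 0.931 and 0.971 across genes, and the closest pair shared 0 genes with equal values above 0, so no library was counted as a repeat of another.

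Alternatives covered other scale factors, pseudocounts of 0.1 and 1, filters, the cage term, left-out mice and cages, an FDR of 0.10 and other windows around Nrg4. Alternatives based on counts were not run. A covariate of Xist level was planned but not run, since Xist was not used here. Sequence comparison used BLAST+ 2.17.0, and figures matplotlib 3.10.9 under Python 3.11.15.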

Results

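RNA of full-thickness distal colon was profiled in 6 WT and 5 Nrg4 knockout (KO) mice that had shared 3 cages. Between 10221 and 10822 genes reached 1 TPM in a mouse. Mitochondrially encoded genes took 19.0% of the summed TPM in KO-1, the lowest share, and 42.9% in KO-3, the highest. The most abundant gene was mt-Co1 in 10 of the mice and Sprr2a2, an epithelial cornified-envelope gene of a multigene family, in WT-7.

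The first question was whether the targeted gene differed between the genotypes. Nrg4 (chromosome 9, 55220222 to 55326844, minus strand, mm10) was listed at 0 TPM in all 11 mice, WT and KO alike. Its level therefore could not be used to check the genotype labels. Erbb4, which encodes the neuregulin-4 receptor, was also near the floor, with 0.00420 ± 0.00464 TPM in WT (SD, n = 6) and 0.00128 ± 0.00287 TPM in KO (SD, n = 5).

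The second question was which genes differed between KO and WT colon. The largest differences were lower values of St3gal4 and Nxpe4 in KO. A true loss of transcript and reads that failed to match the reference transcripts could not be told apart here, as taken up below. St3gal4, a sialyltransferase that adds sialic acid to galactose residues of glycans, had 177 ± 60.7 TPM in WT (SD, n = 6) and 1.19 ± 0.271 TPM in KO (SD, n = 5), a log2 fold change of -6.61 ± 0.22 (limma FDR 4.33e-07). Nxpe4, a member of the neurexophilin and PC-esterase family expressed in colonic epithelium, had 44.8 ± 13.4 TPM in WT and 0.594 ± 0.246 TPM in KO, a log2 fold change of -5.31 ± 0.23 (limma FDR 3.15e-06). Hspa8, the constitutive cytosolic HSP70 chaperone, fell from 244 ± 73.2 TPM to 48.9 ± 13.1 TPM, a log2 fold change of -2.29 ± 0.27 (limma FDR 0.0218). Gm32742, an unnamed gene model outside the naming rule, rose from 0.800 ± 0.0954 TPM to 2.47 ± 0.610 TPM, a log2 fold change of 1.21 ± 0.15 (limma FDR 0.0328). Each of these 4 genes had all KO values on one side of all WT values.

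These 4 genes, 3 lower and 1 higher in KO, were all that passed the threshold among 10756 tested, and all lie on chromosome 9. St3gal4 spans 35046576 to 35119268, Hspa8 40800984 to 40810087, Nxpe4 48162023 to 48400025 and Gm32742 51130307 to 51165517. At an unadjusted p below 0.05 there were 333 genes, 3.10% of those tested, 219 lower and 114 higher in KO. Outside chromosome 9 the smallest adjusted p was 0.142. In the authors' deposited table, 5 transcripts had a q below 0.05, of St3gal4, Nxpe4, Gm32742, Hspa8 and Bco2. With each mouse left out in turn, St3gal4 and Nxpe4 passed in 11 of 11 fits and Hspa8 in 4 (limma FDR 0.00582 to 0.128 over the 11 fits); its call was lost without KO-1, WT-2, KO-3, KO-4, WT-5, WT-6 or WT-11, while its log2 fold change stayed between -2.49 and -2.12. Gm32742 passed in 0 of them; it was tested in 6, with adjusted p of 0.0700 to 0.138, and fell below the filter in 5. Hspa8 has processed pseudogene copies and Nxpe4 spans the related gene Nxpe2 on the opposite strand, so that part of their reads could be shared between genes.

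**Figure D1:**
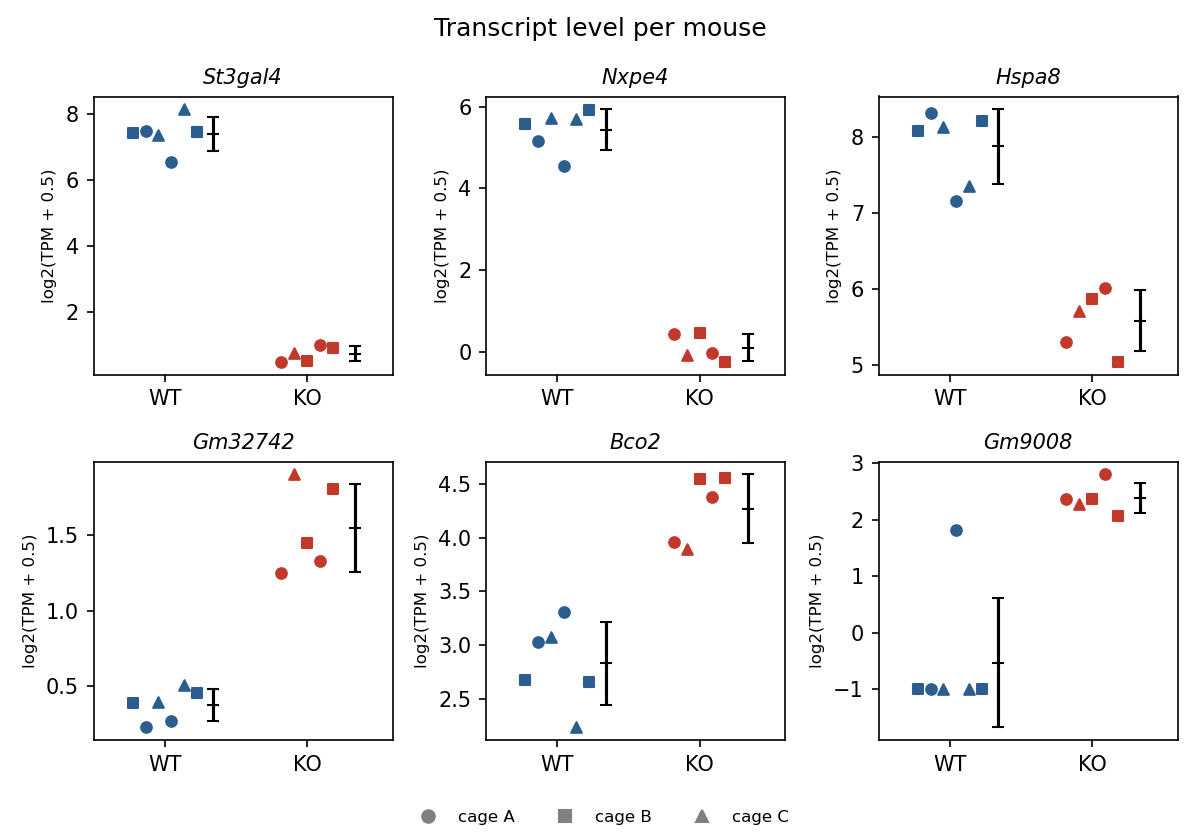
Transcript level per mouse, as log2(TPM + 0.5), for 6 genes in 6 WT (blue) and 5 KO (red) mice; symbols give the cage, and the bar beside each group is its mean ± SD. KO values lie below WT values for St3gal4, Nxpe4 and Hspa8 and above them for Gm32742, Bco2 and Gm9008, with WT-7 at 3.01 TPM of Gm9008 and the other WT mice listed at 0.

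The next genes by p did not pass the threshold. Bco2, which encodes a carotenoid-cleaving oxygenase, had 6.82 ± 1.86 TPM in WT and 19.1 ± 4.18 TPM in KO (limma FDR 0.0702). Mpzl2, a junctional adhesion protein of epithelia, had a log2 fold change of -0.65 ± 0.12, Jaml, a leukocyte adhesion molecule, -1.14 ± 0.25, and Colca2 1.18 ± 0.22. These 4 genes lie on chromosome 9 between 45039799 and 51278569, as does Nme6 farther away at 109832749, with -0.91 ± 0.21. Of the other named genes, Ell3 (0.56 ± 0.11), Fam168a (0.76 ± 0.16), Nfu1 (0.96 ± 0.23), Emcn (0.73 ± 0.17), Col4a1 (0.54 ± 0.14) and Dok7 (0.58 ± 0.15) had positive values. Tbce (-1.03 ± 0.20), Galnt2 (-1.59 ± 0.34), the creatine transporter gene Slc6a8 (-0.36 ± 0.08), Hras (-0.48 ± 0.11), Jmjd6 (-0.60 ± 0.15) and Mrgbp (-1.04 ± 0.26) had negative values. Gm9008, a gene model on chromosome 6 chosen after its values were seen, had the smallest adjusted p outside chromosome 9, with a log2 fold change of 2.84 ± 0.45 and an FDR of 0.142. It passed the threshold when WT-7 was left out.

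A knockout allele can carry flanking sequence of the strain in which it was made, so the position of the called genes relative to Nrg4 was compared. Within 10 Mb of Nrg4, 2 of 134 tested genes passed the threshold, Nxpe4 and Gm32742, against 2 of 10622 elsewhere (two-sided Fisher's exact p = 0.000909, treating genes as independent). At an unadjusted p below 0.05, 16 of the 134 neighbours (11.9%) differed, against 2.98% of the other genes. Hspa8 lay 14.4 Mb from Nrg4 and St3gal4 20.1 Mb. With the 4 called genes left out, the bins of chromosome 9 that start at 40 and 50 Mb had the highest mean squared test statistics of 190 bins of 10 Mb across the genome, 3.78 and 2.73, and the highest elsewhere was 2.14, on chromosome 13. The bin at 30 Mb, which holds St3gal4, then ranked 24, with 1.32. With any single mouse but WT-6 left out, 1 neighbour passed, Nxpe4.

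**Figure D2:**
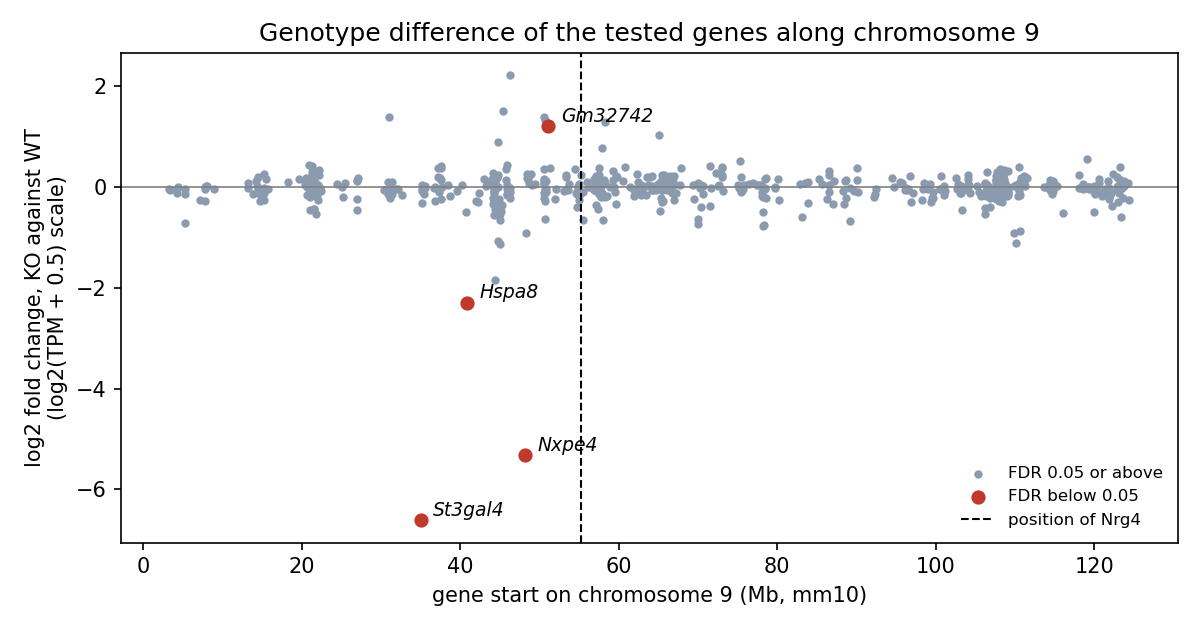
Log2 fold change of KO against WT for each tested gene of chromosome 9, by gene start in Mb (mm10), with the 4 genes past an FDR of 0.05 in red and the position of Nrg4 as a dashed line. The 4 genes start between 35046576 and 51130307, all on the side of Nrg4 towards the start of the chromosome.

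Gene groups were then compared. None of the members of the 34 lists passed the threshold over all genes tested, and 2 lists had a member that passed when adjusted over the list alone. All 13 mitochondrially encoded genes had higher values in KO, such as mt-Co1 at 30559 ± 7708 TPM in WT and 39981 ± 18521 TPM in KO; mt-Atp8 had a log2 fold change of 0.43 ± 0.20 and mt-Co3 0.32 ± 0.19. The list was called by camera (adjusted p = 3.30e-05) and was not with an estimated correlation (adjusted p = 0.973). It had the highest score in KO-3, and without KO-3 its mean log2 fold change went from 0.28 to 0.068 (camera adjusted p = 0.299). Endothelial and lymphatic markers were higher in KO for 8 of 10 members (camera adjusted p = 0.0112, and adjusted p = 0.973 with an estimated correlation). Emcn, an endothelial sialomucin, had 1.28 ± 0.430 TPM in WT and 2.51 ± 0.438 TPM in KO and was the member that passed when adjusted over the list alone; Esam had a log2 fold change of 0.42 ± 0.23. Fibroblast and matrix genes were higher for 21 of 25 members (camera adjusted p = 0.0276, and adjusted p = 0.973 with an estimated correlation), with the basement membrane collagen Col4a1 at 5.05 ± 2.22 TPM in WT and 7.57 ± 1.58 TPM in KO and Postn at -0.91 ± 0.27. Without WT-7 the mean of this list turned from 0.10 to -0.064 (camera adjusted p = 0.877), and that of the endothelial list went from 0.30 to 0.13 (camera adjusted p = 0.207). The endothelial call was also lost without WT-6, KO-8 or KO-9 (mean log2 fold change 0.24, 0.35 and 0.25; camera adjusted p of 0.0624, 0.0723 and 0.208), and the fibroblast call without KO-1, KO-8, KO-9 or WT-11 (mean log2 fold change 0.075, 0.094, 0.041 and 0.079; camera adjusted p of 0.0655, 0.214, 0.656 and 0.288). The other 31 lists were not called (smallest camera adjusted p = 0.116), and fry called 0 of the 34 lists (smallest adjusted p = 0.997).

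**Figure D3:**
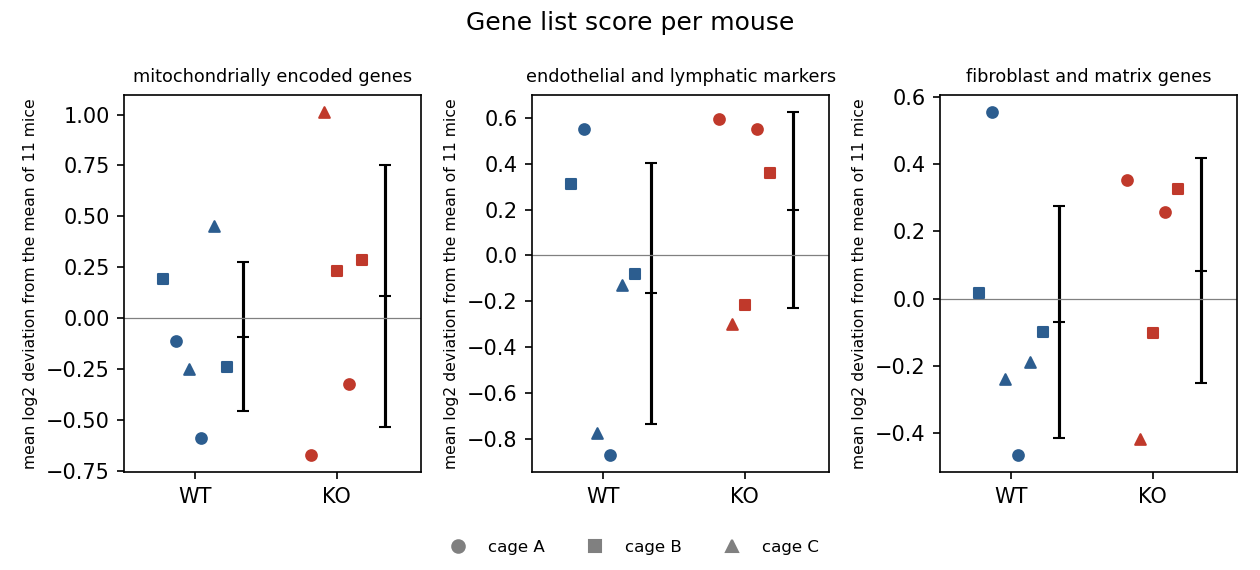
Mean log2 deviation from the mean of the 11 mice for the 3 lists called by camera with a preset correlation, in 6 WT (blue) and 5 KO (red) mice, with symbols for the cage and bars for the mean ± SD. The values of the genotypes overlap in each list, and KO-3 has the highest mitochondrial value, 1.01.

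None of the epithelial groups was called. Of the ErbB receptors and ligands, 9 of 16 were tested, 5 higher and 4 lower in KO. Erbb2 had 27.7 ± 2.74 TPM in WT and 29.8 ± 7.38 TPM in KO, Erbb3 47.5 ± 7.02 and 45.5 ± 11.7 TPM, and Tgfa and Ereg had log2 fold changes of -0.25 ± 0.12 and 0.40 ± 0.22. Absorptive colonocyte markers were split 11 to 11, with Cyp2c55 at 0.32 ± 0.15 and Aqp4 at 0.46 ± 0.27. Goblet cell markers were higher for 14 of 20, with the mucin Muc2 at 168 ± 28.7 TPM in WT and 171 ± 46.0 TPM in KO, Galnt12 at -0.53 ± 0.19 and Creb3l1 at 0.17 ± 0.09. Tuft cell markers were higher for 6 of 9, with Rgs13 at 0.71 ± 0.24 and Avil at 0.48 ± 0.20. Enteroendocrine markers were lower for 10 of 16, with Scg2 at -0.82 ± 0.35 and Tph1 at 0.32 ± 0.17. Stem cell and Wnt target genes were higher for 10 of 17, with Lgr5 at 0.25 ± 0.25 and Ephb2 at 0.24 ± 0.21, and proliferation genes for 20 of 28, with Rrm2 at 0.30 ± 0.17 and Mcm3 at 0.20 ± 0.14. Tight junction and adhesion genes were split 11 to 13, with the desmosomal gene Pkp3 at -0.38 ± 0.11 and Cldn15 at 0.30 ± 0.15. Antimicrobial and barrier genes were split 10 to 12, with Slpi at -0.42 ± 0.24 and Gsdmc4 at -0.19 ± 0.11.

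Immune groups were likewise not called. Interferon response genes were lower in KO for 21 of 27 members (camera adjusted p = 0.116), with Gbp2 at -0.47 ± 0.20 and Ifit1 at -0.53 ± 0.27. Macrophage markers were split 8 to 8, with Mrc1 at -0.27 ± 0.18 and C1qb at -0.31 ± 0.25. Of the T and NK cell markers 2 of 29 passed the filter, Trac and Trbc2, at 0.48 ± 0.95 and 0.47 ± 0.83, and of the B and plasma cell markers 8 of 25, with Cd79a at -1.13 ± 0.93 and Mzb1 at -0.46 ± 0.37. Of the neutrophil and mast cell markers 2 of 20 passed the filter, Cma1 (0.32 ± 0.75) and Ly6g (-0.02 ± 0.22), too few to describe these cells. Pattern recognition genes were higher for 13 of 21, with Irak1 at -0.90 ± 0.55 and Ddx58 at -0.30 ± 0.20. Cytokines and chemokines were higher for 6 of 11, with Cxcl13 at -0.97 ± 0.74 and Ccl8 at -0.55 ± 0.48, and MHC class II genes for 5 of 8, with Ctss at -0.07 ± 0.07 and H2-DMb2 at -0.70 ± 0.87.

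In the metabolic and stress groups, cholesterol synthesis genes were lower in KO for 19 of 25, with Sc5d, itself on chromosome 9 at 42251595, at -0.31 ± 0.10 and Idi1 at -0.36 ± 0.23. Fatty acid and PPAR target genes were lower for 18 of 28, with Scd1 at -0.32 ± 0.21 and Me1 at 0.23 ± 0.16. Unfolded protein response genes were lower for 13 of 23, with Sdf2l1 at 0.18 ± 0.10 and Manf at -0.41 ± 0.23. Apoptosis regulators were split 15 to 15, with Mlkl at -0.28 ± 0.13 and Bid at -0.63 ± 0.34. Circadian clock genes were split 9 to 9, with Ciart at -0.64 ± 0.35 and Arntl at 0.55 ± 0.38, and immediate early genes 11 to 10, with Zfp36 at 0.39 ± 0.33 and Dusp1 at -0.38 ± 0.35.

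Of the groups that mark other tissues or positions along the gut, none was called. Smooth muscle markers were higher in KO for 16 of 19, with Tpm1 at 0.21 ± 0.17 and Kcnmb1 at 0.19 ± 0.19. Enteric neuron and glia markers were higher for 8 of 17, with S100b at 0.20 ± 0.21 and Gfap at -0.25 ± 0.29. Adipocyte markers were lower for 7 of 11, with Acsl1 at -0.19 ± 0.10 and Cidec at -0.69 ± 0.40. Of the skeletal muscle markers 3 of 22 passed the filter, with Acta1 at -0.25 ± 0.36 and Eno3 at 0.12 ± 0.20. Squamous epithelium markers also had 3 of 22, with Anxa8 at -0.56 ± 0.35 and Krt17 at 0.13 ± 0.22. So few members do not describe these tissues. Small intestine and pancreas markers were higher for 6 of 13; Apoc3, an apolipoprotein gene on chromosome 9 at 46232933, had 0.660 ± 1.21 TPM in WT and 3.84 ± 2.47 TPM in KO (2.21 ± 0.59) and was the member that passed when adjusted over the list alone, and Fabp6 stood at -0.65 ± 0.25. Gut Hox genes were higher for 12 of 16, with Cdx2 at 0.43 ± 0.23 and Hoxd11 at -0.67 ± 0.44. Sex chromosome dosage genes were split 2 to 2, with Kdm6a at 0.29 ± 0.14 and Ddx3x at -0.21 ± 0.12.

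The third question was whether cages differed. No gene passed the threshold in the F test on cage (limma; 0 genes, smallest adjusted p 0.0876), and 1303 genes (12.1%) had an unadjusted p below 0.05. The 6 named genes set cage A apart from cages B and C, the same split as that of the Y-linked genes below. Higher in cage A were Cdca5, a cohesion factor of dividing cells (4.43 ± 0.668 TPM against 1.38 ± 0.811 and 0.931 ± 0.0571), the immediate early gene Nr4a1 (21.7 ± 12.3 against 2.77 ± 0.662 and 2.94 ± 0.758) and Nacc1 (29.0 ± 2.33 against 18.7 ± 1.56 and 18.9 ± 1.12). Lower in cage A were Gcnt1 (14.9 ± 2.53 against 25.96 ± 2.69 and 26.6 ± 1.64), the iron exporter gene Slc40a1 (67.7 ± 10.3 against 114.9 ± 4.99 and 127.6 ± 21.9) and Fahd1 (37.6 ± 5.14 against 59.9 ± 4.72 and 67.8 ± 9.90), all as TPM with the SD of 4, 4 and 3 mice. With no filter, 4 genes passed, among them the Y-linked Eif2s3y, Ddx3y and Kdm5d, which the filter on 5 mice removes.

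The Y-linked genes, chosen after their values were seen, divided the cages. Eif2s3y had 27.7 ± 4.36 TPM in cage A (SD, n = 4) and 0.00748 ± 0.0198 TPM in cages B and C (SD, n = 7), Ddx3y 6.62 ± 2.29 and 0.00542 ± 0.0143 TPM, and the X-linked Kdm6a, which escapes X inactivation, 1.78 ± 0.199 and 3.73 ± 0.807 TPM. For these genes the split of cage A from the other cages was the most extreme of 330 (two-sided exact permutation p = 0.00303, adjusted p = 0.00354 over 7 genes); the X-linked Ddx3x gave an exact p of 0.491. The labels give no sex per mouse. Eif2s3y had at least 21.5 TPM in each mouse of cage A and at most 0.0523 TPM in each of the others. By the Y-linked transcripts, cage A thus held males and cages B and C females. A term for these genes would be contained in the cage term, so any difference by sex and any difference of cage A could not be separated in these data.

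The fourth question was whether the genotype difference depended on cage. The F test on the interaction called 2 genes, Ube2j2, a ubiquitin-conjugating enzyme of the endoplasmic reticulum (limma FDR 0.000671), and the histone gene Hist2h3c1 (limma FDR 0.0168), with 427 genes (3.97%) at an unadjusted p below 0.05. Ube2j2 had 0.00494 TPM in KO-3, the single KO mouse of cage C, and at least 26.1 TPM in the other KO mice; its log2 difference between genotypes was 0.09 in cage A, -0.27 in cage B and -6.30 in cage C. The KO arm of cage C is this single mouse, so for Ube2j2 a dependence on cage and a deviation of KO-3 could not be separated. Hist2h3c1, one of several near-identical histone genes, was listed at 0 in KO-3 and in WT-5 and was near 0 in WT-7, and its log2 difference was 3.22 in cage A, 0.50 in cage B and -2.94 in cage C. Cnep1r1, Hsd3b7 and Aspscr1 were also named by the rule and did not pass, and each had its lowest KO value in KO-3. Without cage C, limma called 0 genes (Hist2h3c1 FDR 0.899), and with other single mice left out Ube2j2 passed in 10 of 10 fits and Hist2h3c1 without WT-2, WT-5 or WT-11.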

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

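The tests of splits within cages, of the 10 Mb bins, of the direction of genes near Nrg4, of the St3gal4 fall, of the Rnf26 identity and of the position of WT-7 were chosen after the result was seen.

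The genes of the genotype comparison lay together on chromosome 9, over 35 to 51 Mb. Over splits of the mice into 6 and 5 that ignore cage, grouping by chance could not be excluded for the number of genes called: 5 of 100, the real one included, called as many as the real 4, with a highest other of 279. Over splits that keep the genotype numbers of each cage, which match the cage term of the fit, 2 of 100 called as many, with a highest other of 6. These splits were added after the first result was seen, so they argue against grouping by chance but do not exclude it. For the number within 10 Mb of Nrg4 it could be excluded in both, where 1 of 100 splits, the real one, reached 2 genes; the highest other was 1 when cage was ignored and 0 within cages. The splits with 279 calls both set WT-5 and KO-8 against KO-1 and WT-7 in cage A, a structure of these samples that crosses genotype. Those with 14 calls both set KO-3 against WT-6 and WT-10 in cage C. All of them put the other cages whole into one group, so under the cage term they compared mice of a single cage. The share of 5 of 100 rests on these repeated comparisons, so for the number of genes the splits that ignore cage decide little.

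One hypothesis for the cluster is donor-strain DNA carried along with the knockout allele: with the called genes left out, 2 of the 3 bins of 10 Mb with the highest mean squared statistic lay there, those at 40 and 50 Mb, while the bin of St3gal4 at 30 Mb ranked 24 of 190. A failure of donor-strain reads to match the reference transcripts would lower a gene, but reads assigned to a similar transcript instead could raise that one. Of the 30 genes past an unadjusted limma p of 0.05 within 20 Mb, 40% were higher in KO. Genes elsewhere passed that p at 2.88%, against 12.0% of the 249 neighbours, so part of the 30 may be chance picks. The direction of the 12 higher genes therefore does not decide on this explanation. For the genes that fell, such as St3gal4 at -6.61, that explanation and a true loss cannot be told apart, since no donor sequence was used here. An effect of the loss of Nrg4 itself on these genes remains open and was not tested.

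Gm9008, on chromosome 6, stood out in WT because WT-7 had 3.01 TPM and the other 5 were at 0, while KO mice had 4.77 ± 1.03 TPM (SD, n = 5). Reads shared with Hspa8 were tested first and are argued against: 0% of Gm9008 aligned to it. The only other transcript compared was that of Rnf26, a chromosome 9 gene 11.1 Mb from Nrg4. Gm9008 aligned to it at 99.1% identity over 98.5% of its length, so Gm9008 may collect reads of a donor copy of Rnf26. Whether other transcripts match as well was not tested. The matching loss of Rnf26 was -1.08 TPM against a gain of 4.27 TPM in Gm9008, and with Rnf26 at 6.57 ± 2.38 TPM in WT and 5.49 ± 2.25 TPM in KO (SD) this leaves the explanation open. A change of Gm9008 itself remains open.

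WT-7 lay between the genotypes at 3 of the 4 called genes, with 47.6% of the mean of the other WT mice for St3gal4, 46.9% for Nxpe4 and 53.6% for Hspa8, and within the WT range at Gm32742 (0.705 TPM). Of the chromosome 9 genes next by p, WT-7 had the highest WT value of Bco2 (9.41 TPM). It had the lowest WT values of Mpzl2 (23.1 TPM) and Jaml (0.932 TPM). At Colca2 (1.55 TPM) it lay within the range of the other WT mice. Over 17 chromosome 9 genes picked without WT-7, its median position from the WT mean (0) to the KO mean (1) was 0.670, above the other WT mice (-0.187 to 0.369) and just below KO-3 (0.693) and KO-1 (0.725) when those were left out in the same way. Its quartiles, 0.527 and 0.952, overlap among others those of KO-3 (0.359 and 1.00), KO-1 (0.653 and 0.997) and WT-5 (0.0879 and 1.20). Over genes outside chromosome 9 picked in the same way, its median position was 0.787 (60 genes), with WT-5 at 1.06. The other WT mice stood there at 0.258 to 0.404. Those genes may largely be chance picks, and KO-8 stood at -0.06 over its own. They therefore cannot show whether a position towards KO was particular to chromosome 9. The range first set for a single donor copy, itself chosen after the result was seen, held the median position of WT-7. A rule that its quartiles must not overlap those of other mice was added later. Under that rule a single donor copy and other reasons for the position of WT-7 cannot be told apart. RNA of a deposited KO mouse mixed into WT-7 is argued against: the highest correlation of WT-7 with a KO mouse over 110 immunoglobulin segments was -0.0197, below the 0.103 of another WT and KO pair.

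Single mice stood far from the rest of their genotype in 17 of 202 groups of values, 8.42% where chance gives about 5%, and 8 of the 17 were in KO-3. That count is not independent of how genes were named, since the interaction genes were chosen for their cage C values. KO-3 was low for Ube2j2 (0.00494 TPM), Hist2h3c1 (0), Cnep1r1 (0.723), Hsd3b7 (0.660), Aspscr1 (0), the mast cell chymase gene Cma1 (0.0114) and Postn (0.831), and high for Ifit1 (9.23). Some of these values are not particular to KO-3: Cma1 was also near 0 in WT-5 (0.0513) and WT-6 (0.00554), Hist2h3c1 in WT-5 and WT-7, and Ifit1 had 10.4 in WT-10. KO-1 was high for Trbc2 (28.9), Trac (25.8) and Cd79a (38.9), where the other KO mice reached at most 3.11, 1.76 and 1.82, though WT-11 had 13.9 for Trbc2 and WT-2 had 24.5 for Cd79a. The immediate early gene Dusp1 was high in WT-5 (51.5) and in KO-8 (31.4). WT-10 was high for Hras (52.3), WT-7 for Mlkl (10.5) and WT-11 for Cidec (7.06), all in TPM. The interaction of genotype and cage passed for Ube2j2 (limma FDR 0.000671) and Hist2h3c1 (limma FDR 0.0168), with a cage C arm of KO-3 alone. Without cage C neither passed: the log2 differences in cages A and B were 0.09 and -0.27 for Ube2j2, and 3.22 and 0.50 for Hist2h3c1 (limma FDR 0.899).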

How the results depend on the processing

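Runs with another filter on 5 TPM, a robust fit, single transcripts, WT-5 and KO-8 both left out, each mouse left out near Nrg4, other settings of the lists, at least 1 TPM in 3 mice for cage, and cage subsets and left-out mice on the same genes were added after seeing the data. The 4 genes called between genotypes were the same genes under both sets of scale factors, both pseudocounts and a robust fit; at a mean of at least 5 TPM Bco2 was called in place of Gm32742. The count was 2 with no filter and with WT-5 and KO-8 left out, 1 with cage A, B or C left out (St3gal4) and 0 in cage A or cage B alone; without single mice it was 2 to 4. In the cage subsets the filter removed Nxpe4 and Gm32742, and in single cages also St3gal4, from the test. It asked for at least 1 TPM in 5 mice with a cage left out and in every mouse of a single cage. With the same genes tested as with all mice, the counts were 4 without cage A, 2 without cage B or C, 0 in cage A alone and 3 in cage B alone, with St3gal4 and Nxpe4 called in each but cage A alone, and 2 calls outside chromosome 9 without cage A (Sspn, Gm9008) and 1 in cage B alone (Pcbd2); left-out mice changed Hspa8 from 4 to 3 fits passed, and Gm32742 passed in 0 of 11. The genotype count was 5, with Bco2 added, without the cage term and at an FDR of 0.10. Single transcripts gave 4 calls, 3 of them shared, with Pgap2 on chromosome 7 as the other. The 3 lists called became 1 with no filter, 0 with an estimated correlation and 0 by fry, 5 with WT-5 and KO-8 left out, and 1 to 8 without single mice. The mean of fibroblast and matrix genes reversed to -0.064 without WT-7, the lowest value, and reached 0.213 without WT-5. Genes called near Nrg4 numbered 1 within 5 Mb, 3 within 20 Mb, 3 with no cage term, and 1 to 2 without single mice. Cage calls numbered 4 with no filter, 2 with no genotype term, 5 with at least 1 TPM in 3 mice, and 0 to 2 without single mice. Interaction calls numbered 49 with no filter and 0 without cage C, where the interaction has fewer samples, and 1 to 5 without single mice. The cause of the other changes was not tested. Grouping by chance could not be excluded for the lists, where 91 of 100 splits, and 91 of 100 within cages, called at least the real 3 (highest other 15 in both). The real cage count of 0 is reached by every regrouping (100 of 100; highest other 9), so regrouping decides nothing there. No paired analysis was possible because the genotypes share no mouse numbers; cage was the block. Count-based tests, factors and filters were not run because the table holds TPM, which also leaves the depth unknown, and the Xist covariate was not run.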

Other observations

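The gene scores here were chosen after the data were seen. Immediate early genes were high in 2 mice of cage A, one of each genotype. Egr1 stood at 354 TPM in WT-5 and 75.04 TPM in KO-8 and at most 7.30 TPM in the other 9 mice. The ErbB ligand genes Areg (208 and 110 TPM) and Hbegf (74.5 and 28.2 TPM) were high in the same mice, and the clock output gene Dbp was low in them, at 1.70 and 1.97 TPM. Across the 11 mice, the mean of 5 ErbB ligand genes followed that of the immediate early genes (Pearson r = 0.97, permutation p = 7.0e-05, adjusted 0.00021; Spearman rho = 0.84, permutation p = 0.00231, adjusted 0.00693, over 3 relations), and r was 0.78 without WT-5 and KO-8. Over the 7 mice of cages B and C it was 0.40, and cage A holds too few mice for a value. The ligand genes were picked from these values, so the p describes what was already seen; permuted within cages it was 0.0135. Clock output genes went the other way (r = -0.88, permutation p = 0.00151, adjusted 0.00226; rho = -0.77, permutation p = 0.00762, adjusted 0.00848), with r of -0.57 without those mice and -0.20 in cages B and C (permutation p within cages 0.0564), so this relation rests largely on WT-5 and KO-8.

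T cell and B cell receptor genes were both highest in KO-1, with Trac at 25.8 TPM and Cd79a at 38.9 TPM. Cd79a was also high in WT-2 (24.5 TPM) and WT-7 (20.8 TPM), where Trac had 2.72 and 1.12 TPM; WT-7, with a T cell score of -0.43 and a B cell score of 2.04, went against the relation below. The mean of 5 T cell genes and that of 5 B cell genes correlated across the 11 mice (r = 0.74, permutation p = 0.0117, adjusted 0.0117; rho = 0.76, permutation p = 0.00848, adjusted 0.00848). Without KO-1 and WT-11, r was 0.59, and in cages B and C it was 0.69 (permutation p within cages 0.0270).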
